A study of Mus musculus with 4 samples.

How the data were processed

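Single-cell RNA was measured in 4 libraries of cells from C57BL/6 mouse aorta: aged descending intima a and b, young arch intima and aged adventitia. Per the labels, the aorta was perfused and cleaned of adventitia, opened flat and treated with trypsin. The endothelium was then scraped off in the presence of actinomycin D, and red cells were lysed. Each descending library pooled 6 mice and the arch library 8 mice, and the number for the adventitia is not stated. The labels repeat the intimal protocol for the adventitial library. Ages were taken from the sample titles, the sex is not given, and the labels do not say that libraries a and b came from separate animals beyond the 6 mice each.

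Per the submitters' processing notes, libraries were made with the 10x Chromium Single Cell 3' kit v2 and reads were aligned and counted with Cell Ranger 2.1.2 on mm10. The deposited files hold the authors' UMI counts per gene and barcode, after their calling of cells. Each file listed the same 27998 genes, of which 27645 had a symbol and 353 did not. The annotation release was not stated. The files held 2095, 2178, 2187 and 9347 barcodes and 13715023, 13181305, 18624525 and 29370967 UMIs, in the order given above. Median UMIs per barcode were 5113, 4808.5, 6989 and 2524. Gene coordinates were taken from GENCODE M21 (GRCm38).

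Barcodes were kept with at least 200 genes and at most 10% mitochondrial UMIs, which left 2030, 2132, 2172 and 8497. Doublet scores were computed per library with Scrublet as built into scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold called 6, 23, 17 and 2 barcodes, which was 0.0235% of the adventitial barcodes. The barcodes with the highest scores were therefore called instead, as many as the loading predicts with ties included, which removed 42, 41, 58 and 593. This choice was made after the automatic calls were seen. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3.

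The 4 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2000 variable genes were scaled and reduced to 30 principal components, and a shared-neighbour graph of 15 neighbours was split by the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from 23 marker lists. A marker counted when at least 20% of the cluster's cells had a UMI and its level was at least 2 times the background. The background was percentile 25 over the clusters of the library that held most of the cluster. The level also had to reach 10% of the highest cluster. A name needed 3 markers. A cluster stayed unnamed when its 10 leading genes or its markers pointed to another class. Names such as T-cell-like describe RNA and were not checked by protein. Classes with at least 20 cells in each library used were tested: macrophage, endothelial and fibroblast. Macrophages and endothelial cells were named from such markers, so a difference in those genes between them followed from the naming.

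Macrophage-like cells of the 4 libraries were clustered again at resolution 0.5, and subgroups were named from the Lyve1 resident and intima resident lists. Shares of cells are given with 95% exact Clopper-Pearson intervals and levels with 95% exact Poisson intervals, which cover counting error and not the spread between animals. Shares of cells with a UMI of a gene depend on depth, so they were also computed with each cell thinned to 2000 UMIs, leaving out cells with fewer. A group with no UMI was set to a floor of 3 counts over the group for a bound on its fold change.

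Counts were summed per library and class. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Macrophages were compared with endothelial cells over 6 sums of the 3 intimal libraries with the library as a block, which left 2 residual degrees of freedom. The arch and the adventitia were each compared with the 2 descending libraries in a fit of all 4 libraries with 1 residual degree of freedom. Such p-values assume that a lone library varies as the descending libraries do. No paired analysis was possible because the groups share no replicate numbers. The 2 descending libraries shared 7 of their 2095 and 2178 barcodes, so they were not copies of 1 library. Their p-values draw on the spread between these libraries, which may be technical. This spread was pooled over genes by edgeR, with 60.6 prior degrees of freedom for endothelial cells and 14.8 for fibroblasts. For macrophages the prior was infinite, so their p-values rested on the pooled spread and not on a gene's own.

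The comparisons, the 18 fixed gene lists, the naming rule and most alternatives were set before the data were examined. The naming rule took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes that passed. They had at least 50 CPM in the higher arm and the same direction in every pair of libraries. Mitochondrial, ribosomal, haemoglobin, predicted, Xist and Y-linked genes were left out. In comparisons of a class between libraries, genes with over 5 times more CPM in another class of the same library were left out too. The lists covered anticoagulant and fibrinolytic genes, procoagulant and antifibrinolytic genes, scavenging and engulfment, MHC class II presentation, intima resident macrophages, Lyve1 resident macrophages, lipid handling, inflammatory cytokines and NF-kB, interferon response, laminar flow, disturbed flow, mesenchymal transition, senescence, extracellular matrix, endothelial lipid uptake and transport, proliferation, dissociation and immediate early genes, and haemoglobin. List medians were set against 10000 random lists matched on expression in 20 bins, which describes the libraries at hand. Examples from a fixed list were taken by smallest adjusted p, so genes said to lead a list need not have its largest changes. Lists of clock genes, Hox genes and thymocyte genes were added after results had been seen.

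The edgeR fits were tested on simulated data with the depths and designs of each comparison and 200 changed genes. Changes of 2-fold, 4-fold and 8-fold were recovered in 29.9%, 74.6% and 84.8% of cases for macrophages against endothelial cells (12042 genes), with 5.26% of calls false. For arch endothelial cells (12978 genes) the values were 77.6%, 94.0% and 97.0%, with 4.79% false, and for adventitial endothelial cells (13005 genes) 26.9%, 59.7% and 75.8%, with 1.82% false. For arch macrophages (7029 genes) they were 11.9%, 67.2% and 77.3%, with 5.45% false, and for adventitial macrophages (7025 genes) 16.4%, 74.6% and 69.7%, with 7.76% false. For arch fibroblasts (11009 genes) they were 40.3%, 79.1% and 84.8%, with 3.55% false, and for adventitial fibroblasts (11015 genes) 53.7%, 83.6% and 90.9%, with 4.40% false. In these simulations the lone library varied as the others did, all genes shared the same dispersion and only 200 genes changed. The shares of false calls need not hold for the real data, where genes vary by different amounts.

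Alternatives were DESeq2 1.42.0 with its Wald test, its size factors in the edgeR fit, no filter on low counts, no doublet removal, Leiden resolutions 0.5 and 2.0, each library clustered on its own, a stricter cell filter (at least 500 genes and at most 5% mitochondrial UMIs), equal cell numbers per library, no library block, a fit of only the 3 libraries compared, leaving out each library in turn, and list members of at least 10 CPM. Tests of each macrophage subgroup alone, and of endothelial cells without the cluster with raised lymphatic markers, were added after results had been seen. The result of 1 gene is not reported. Overlaps between the arch and adventitial gene sets were left out because both used the same descending libraries.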

Results

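Single-cell RNA sequencing was deposited for 4 libraries of C57BL/6 mouse aorta. Intimal cells of the aged descending aorta filled 2 libraries, each pooled from 6 mice. Intimal cells of the young aortic arch filled 1 library pooled from 8 mice, and aged adventitia filled 1 library. After cell filters and doublet removal, 1988, 2091, 2114 and 7904 cells were analysed in the order given. Their median depths were 5198.5, 4872, 6952 and 2476 unique molecular identifiers (UMIs) per cell.

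The scraped intima was mainly endothelium, with a small macrophage population, while the adventitial library was rich in lymphocytes and fibroblasts. Endothelial cells made up 74.6% (72.7 to 76.5) and 61.7% (59.6 to 63.8) of the descending libraries and 58.9% (56.8 to 61.0) of the arch library, with 95% exact Clopper-Pearson intervals that cover counting error only. In the adventitia the endothelial share was 4.38% (3.94 to 4.85). Macrophage-like cells made up 4.07% (3.25 to 5.04) and 3.35% (2.62 to 4.21) of the descending libraries, 5.44% (4.51 to 6.49) of the arch library and 8.46% (7.86 to 9.10) of the adventitial library. Fibroblast-like cells were the second largest intimal class, at 15.3%, 29.5%, 19.5% and 18.1% in the same order. When each library was clustered on its own, the macrophage-like shares of the 2 descending libraries were 5.08% and 4.64% and that of the arch library was 7.0%.

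Lymphocytes were scarce in the descending intima and common in the adventitia. T-cell-like cells took 0.855% and 0.861% of the descending libraries, 7.62% of the arch library and 24.5% of the adventitial library. B-cell-like cells took 0.151%, 0.909%, 0.284% and 18.3%. Red-cell-like barcodes took 2.06%, 0.622%, 2.60% and 9.46%. Mesothelial-like cells numbered 2, 0, 44 and 164, monocyte-like cells 10, 10, 1 and 182, and natural killer-like cells 3, 3, 3 and 198. Smooth-muscle-like cells numbered 2, 4, 16 and 13, and neutrophil-like cells 1, 0, 1 and 119. Plasma-like cells (234), mast-like cells (21) and Schwann-like cells (24) were found in the adventitial library only.

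**Figure D1:**
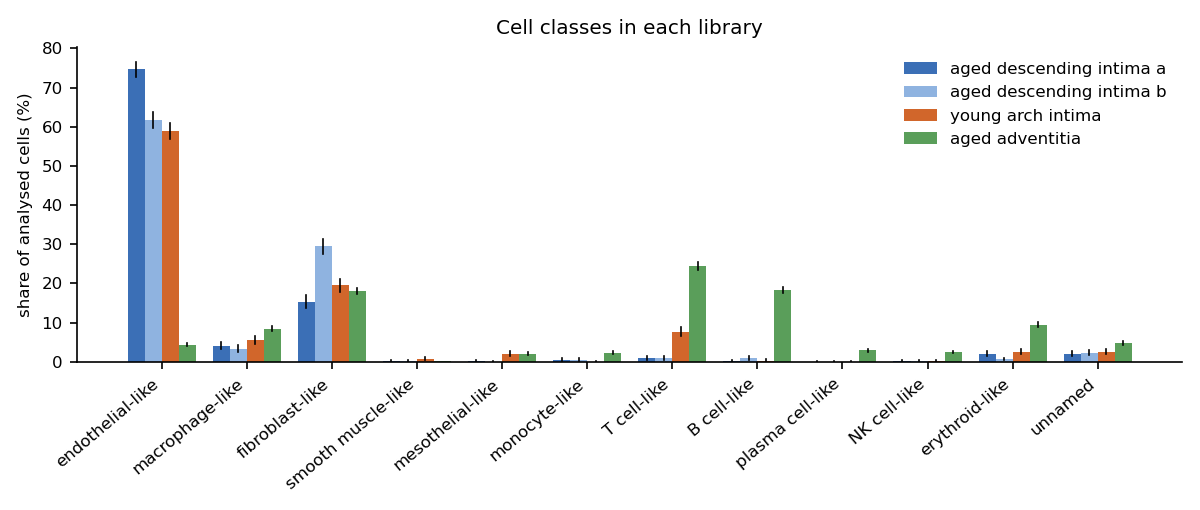
Share of analysed cells per library for each cell class. Bars give the share in percent and whiskers the 95% exact Clopper-Pearson interval, which covers counting error only. Each library is shown on its own: aged descending intima a and b, young arch intima and aged adventitia.

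The intimal macrophages fell into 2 types that were named from gene lists fixed beforehand. The first carried the Lyve1 resident programme known from the adventitia, and the second carried the programme described for macrophages that live in the intima. No adventitial cell clustered with the second type, which was the larger type in the arch. The Lyve1 type made up 70.4% (59.2 to 80.0) and 72.9% (60.9 to 82.8) of macrophage-like cells in the descending libraries, with 95% exact intervals. It made up 34.8% (26.1 to 44.2) in the arch and 41.7% (37.9 to 45.5) in the adventitia. The intima resident type made up 29.6% (19.99 to 40.8) and 25.7% (16.0 to 37.6) in the descending libraries and 65.2% (55.8 to 73.9) in the arch, where it numbered 24, 18 and 75 cells. Among 669 adventitial macrophage-like cells it was seen 0 times, where 3 cells would have been a share of 0.448%. As a share of all analysed cells it was 1.21%, 0.861% and 3.55%. The Lyve1 type joined 2 clusters that both matched its list: 278 of the 279 adventitial cells lay in one, and all intimal cells of the type lay in the other with 1 adventitial cell. In the adventitia 390 macrophage-like cells, 58.3% of the class, matched neither list. The clusters split almost wholly by library and no batch correction was made. The 0 adventitial cells of the intima resident type may therefore partly reflect the clustering. Taken as a class, without subgroups, adventitial macrophages also had far less Mmp12 and Itgax RNA than descending ones.

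**Figure D2:**
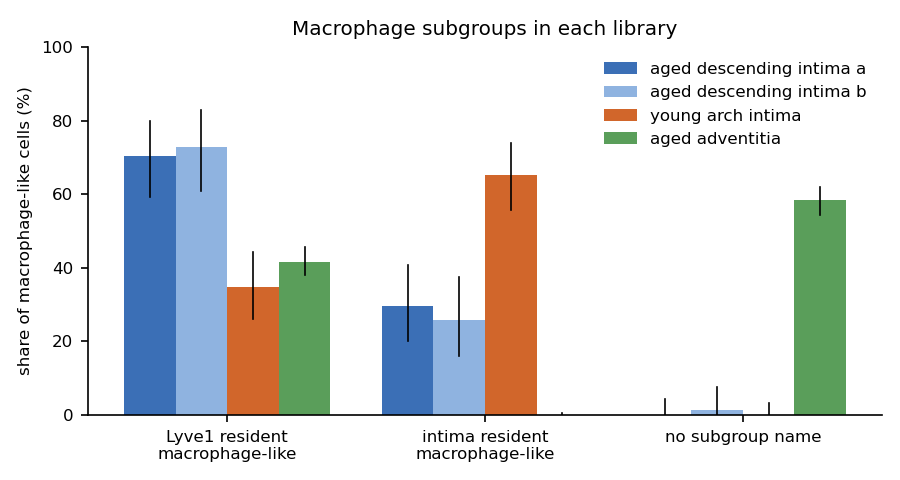
Share of macrophage-like cells in each subgroup, per library. Bars give the share in percent and whiskers the 95% exact Clopper-Pearson interval, which covers counting error only.

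The genes that name a subgroup describe its identity. Itgax, the integrin CD11c (GRCm38 chromosome 7, 128129547 to 128150657), was present at 188, 191 and 180.2 CPM, the counts scaled to equal library totals, in the intima resident type of descending a, descending b and arch. Itgax had 0 UMIs in the Lyve1 type of the same libraries. An Itgax UMI was found in 45.8%, 61.1% and 73.3% of intima resident cells, whose median depths were 4572, 4580.0 and 8973 UMIs. As background it was found in 0.0674%, 0.155% and 0.963% of endothelial cells at median depths of 5737, 5373 and 8394. With every cell thinned to 2000 UMIs the intima resident shares were 36.4%, 18.8% and 29.3%. The metalloprotease Mmp12 stood at 3057, 2269.9 and 1577 CPM in this type. In the Lyve1 type, Lyve1 stood at 1000.4, 1384 and 1073 CPM and at 747 CPM in the adventitia. F13a1, which encodes a subunit of the fibrin cross-linking factor XIII, stood at 1731, 2583 and 1914 CPM in the intimal Lyve1 type.

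Genes that act on clots were spread over both macrophage types and the endothelium. Plau, the urokinase plasminogen activator, was detected at 28.1 CPM (5.80 to 82.2), 21.2 CPM (2.57 to 76.6) and 8.86 CPM (3.25 to 19.3) in the intima resident type, from 3, 2 and 6 UMIs, with 95% exact Poisson intervals. In the Lyve1 type it stood at 4.28, 3.92 and 9.67 CPM from only 1, 1 and 2 UMIs, and in endothelial cells at 0, 0.339 and 0.249 CPM. F3, which encodes tissue factor and starts coagulation, had 0 UMIs in both intimal types, and stood at 76.4 CPM in the adventitial macrophages that matched neither list. Vwf and Nos3 belonged to the endothelium, where Vwf stood at 1043, 995 and 746 CPM and Nos3 at 366, 339 and 253 CPM.

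**Figure D3:**
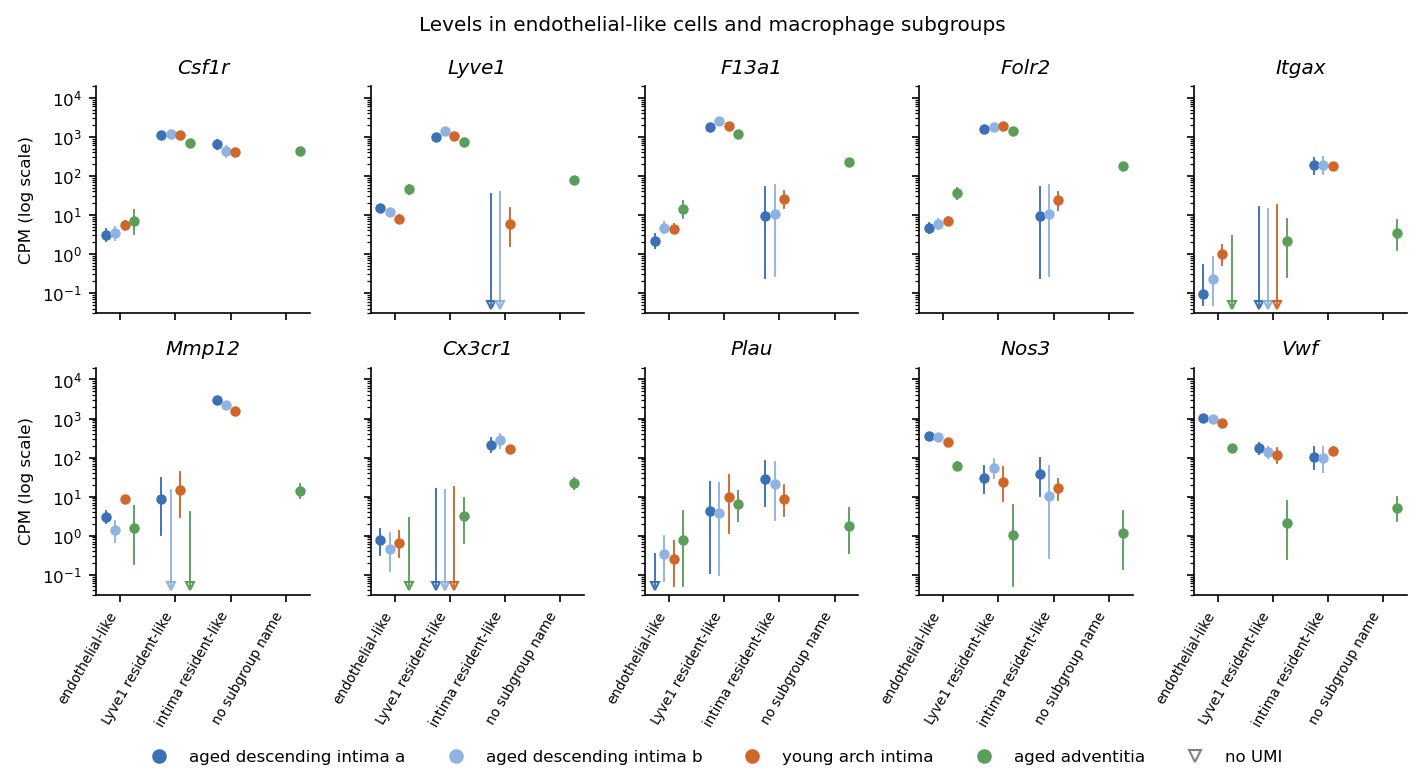
Expression of 10 genes in each macrophage subgroup and in endothelial cells, per library. Points give CPM on a log scale with 95% exact Poisson intervals, which cover counting error only. Open triangles at the axis floor mark groups with no UMI of the gene.

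Intimal macrophages were set against the endothelial cells of the same 3 libraries. The macrophages expressed the machinery to take up dead cells and debris, to present antigen and to send inflammatory signals. The endothelium expressed more of the genes that keep the vessel surface free of clots, and also more of those that promote a clot. Matrix genes and flow-responsive genes also belonged to the endothelium. Of 12035 genes tested, 2082 were higher and 2516 lower in macrophages by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the library as a block and n = 3 libraries. The genes named by the rule had the same direction in all 3 libraries.

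The largest rises by the naming rule included receptors for debris, complement and chemokines. Adap2, which encodes a GTPase-activating protein (GRCm38 chromosome 11, 80154105 to 80178958), led them (log2 fold change 9.22 ± 0.47 SE, edgeR adjusted p = 1.16e-16). Adap2os, a transcript that overlaps Adap2, rose with it (9.09), and the labels do not state whether counting used the strand. The other 8 were the haemoglobin scavenger Cd163 (9.07), the C5a receptor C5ar1 (8.86), the phospholipase Pla2g2d (8.85), the chemokine receptor Ccr1 (8.74), the mannose receptor Mrc1 (8.72), the phosphatidylserine receptor Timd4 (8.71), the lectin Cd209g (8.70) and Fgd2 (8.63). The largest falls were the Notch ligand Dll1 (-5.38), Plac9b (-4.93), the collagen Col8a1 (-4.58), the transcription factor Mecom (-4.43), Perp (-4.29), Net1 (-4.21), the growth factor Bmp4 (-3.95), Clic5 (-3.94), Gata3 (-3.94) and Ushbp1 (-3.91).

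The clotting genes split between the cell types. In the anticoagulant and fibrinolytic list 2 of 12 rose and 6 fell, with falls in the nitric oxide synthase Nos3 (-3.15), the protein C receptor Procr (-2.82) and the prostacyclin synthase Ptgis (-2.58), and a rise in the clearance receptor Lrp1 (2.23). The thrombin-binding Thbd fell (-2.04). Plau rose (log2 fold change 5.80 ± 0.97 SE, edgeR adjusted p = 1.12e-05; GRCm38 chromosome 14, 20836660 to 20843385), from 0.196 CPM in endothelial cells to 9.77 CPM in macrophages. In the procoagulant and antifibrinolytic list 2 of 11 rose and 6 fell. F13a1 (8.38) and the thromboxane synthase Tbxas1 (7.34) rose, while Thbs1 (-3.07), the thrombin receptor F2r (-3.69) and Vwf (-2.40) fell. The median log2 fold changes of these 2 lists were -0.70 and -1.89 with genes lacking UMIs held at their bound.

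Scavenging, antigen presentation and inflammatory genes were mostly higher in macrophages. In scavenging and engulfment 16 of 18 rose and 1 fell (median 7.39), with Cd163, Mrc1, Itgb2 (7.09) and Timd4 lowest in adjusted p. In MHC class II presentation 12 of 13 rose and none fell, and 13 rose when adjusted over the list alone (median 4.70), led by Cd86 (7.84), H2-Eb1 (5.03) and Cd74 (5.80). In inflammatory cytokines and NF-kB 15 of 16 rose and none fell (median 7.06), led by Ccl2 (7.20), Tnf (7.55) and Ccl3 (8.51). In interferon response 6 of 13 rose and none fell, among them Cxcl10 (5.34) and Rsad2 (3.79). Tested by type, a choice made after the class result, 10 of 13 interferon genes rose in the Lyve1 type, while in the intima resident type 1 of 12 rose and 5 fell. In lipid handling 13 of 17 rose and 3 fell, led by Mmp12 (8.21), Lgals3 (5.96) and Trem2 (7.12). In endothelial lipid uptake and transport 4 of 8 rose and 3 fell, with Cd36 (6.92) and Lpl (5.33) higher and Cav1 (-3.25) lower. The class and its subgroups were named from genes such as those of the 2 resident lists, so a rise of these lists against endothelial cells followed from the grouping: all 14 tested genes of the Lyve1 resident list rose, and 9 of 10 of the intima resident list rose and 1 fell, with Itgax at 7.80, Csf1r at 7.93 and Cx3cr1 at 7.41.

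Vessel-wall programmes moved toward the endothelium. In the laminar flow list 2 of 12 rose and 8 fell, led by a rise in the haem oxygenase Hmox1 (5.40) and falls in the connexins Gja5 (-3.67) and Gja4 (-2.81). The flow-induced factor Klf2 did not pass in the class (-0.47, edgeR adjusted p = 0.0513); by type it was lower in the intima resident type (-1.50) and did not pass in the Lyve1 type (-0.08). In the disturbed flow list 2 of 14 rose and 11 fell, with falls in Bmp4, Ccn1 (-3.11) and Edn1 (-3.52). In extracellular matrix 12 of 16 fell and 13 fell when adjusted over the list alone, led by the elastin gene Eln (-3.34), Fbln5 (-3.24) and Bgn (-2.73). In mesenchymal transition 3 of 10 rose and 7 fell, with a rise in Zeb2 (2.56) and a fall in Fn1 (-2.21). In senescence 5 of 10 rose and 1 fell, with rises in Gdf15 (3.70) and Cdkn2a (8.02). All 10 tested genes of proliferation rose, among them Pcna (1.74) and Birc5 (3.59), but by type 10 of 10 rose in the intima resident type (median 4.11) and 1 of 8 in the Lyve1 type (median 0.43). In the dissociation and immediate early list 11 of 16 rose and 2 fell, led by Atf3 (4.95), and all 4 haemoglobin genes rose (median 1.85). Pecam1, from the endothelial marker list, stood at 320.1 CPM in macrophages against 3477 CPM in endothelial cells. Whether this was free RNA from endothelial cells or RNA of the macrophages was not tested. With DESeq2 the number of genes lower in macrophages was 1520, and with the intima resident type alone the number higher was 1373.

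The arch was young and the descending aorta aged, and each arch value came from 1 library, so region, age and library could not be told apart. The p-values rest on 1 residual degree of freedom and assume that the lone arch library would vary as the 2 descending libraries did. They also rest on a spread pooled over genes, more than on a gene's own spread between the descending libraries.

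Arch macrophages carried more antigen presentation and inflammatory signal RNA and less of the Lyve1 resident programme than descending macrophages. The class was tested as a whole, and its balance of the 2 types differed between the libraries. Of 7310 genes tested, 203 were higher and 206 lower in the arch (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these 409 genes, 48 were over 5 times higher in another class of the arch or descending libraries. DESeq2 called 79 genes, with 12 of the 20 genes named by the rule among them, and with no filter on low counts 208 were called. Within the Lyve1 type alone 48 genes passed, and within the intima resident type alone 26.

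The antigen presentation list rose in the arch, with 6 of 12 up and 8 up when adjusted over the list alone. Lowest in adjusted p were Cd74 (1.45), H2-Ab1 (1.46), H2-Aa (1.44) and H2-Eb1 (1.35). In the inflammatory list 9 of 18 rose and 3 fell, with a rise in Tnf (1.69) and falls in the chemokines Ccl8 (-3.62), Ccl7 (-2.36) and Ccl2 (-1.75). In the interferon list 1 of 12 rose and 3 fell, among them Ifitm3 (-1.23) and Rsad2 (-2.04). In scavenging and engulfment 1 of 18 rose and 8 fell, with falls in Mrc1 (-1.72), Gas6 (-1.71) and Timd4 (-1.89). All 14 tested genes of the Lyve1 list fell (median -1.62; Lyve1 -1.63), and 6 of 10 of the intima resident list rose and 1 fell (median 1.17; Itgax 1.42 ± 0.35 SE, edgeR adjusted p = 0.00187). In the anticoagulant list genes moved both ways, with rises in Ptgis (1.72) and Procr (1.47), both lower in macrophages than in endothelial cells. In the procoagulant list 2 of 13 fell, F13a1 (-1.62) and Tbxas1 (-1.11). In lipid handling 3 of 16 rose and 6 fell, and Klf4 fell (-1.15).

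The largest rises by the naming rule were Myl9 (at least 13.8-fold, with 0 UMIs in descending macrophages), Ppbp (5.83), Acta2 (3.93), Bcas3 (3.03), the cytokine Il1a (2.92), the lectin Cd207 (2.72), Ocstamp (2.66), the metalloprotease Mmp14 (2.43), H2-M2 (2.36) and the NF-kB inhibitor Tnfaip3 (2.18). Falls were largest for the chemokine Cxcl13 (at least 76.3-fold, with 0 UMIs in the arch), the complement receptor Vsig4 (-4.42), Cdkn2a (-4.02), Ccl8, C4b (-2.80), Cd209b (-2.72), Cd38 (-2.65), Ednrb (-2.62), Ccl7 and Ecm1 (-2.36). RNA of other cells was higher too, in matrix and haemoglobin genes. The 16 smooth-muscle-like cells of the arch were too few for the screen, and platelets were no class in it. Myl9 and Acta2 could therefore not be screened for RNA from smooth muscle cells, nor the platelet marker Ppbp for RNA from platelets. Sparc (2.58) and Col3a1 (2.75) were over 5 times higher in fibroblasts. Hba-a1, Hba-a2 and Hbb-bs were higher in the arch than in descending b but not than in descending a. Hba-a1 stood at 1744, 205 and 1661 CPM in macrophages of descending a, descending b and arch.

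Subgroup-alone tests were chosen after the class result had been seen. In these tests too, Acta2 was not screened for RNA from smooth muscle cells. In the Lyve1 type, Acta2 (4.57) and H2-DMa (1.95) were higher in the arch and Vsig4 (-2.93) and Ccl8 (-2.19) lower, while Lyve1 itself did not pass (-0.15). In the intima resident type, Acta2 (3.45), Sparc (2.99), Vim (2.47) and Sfrp1 (2.17) were higher, of which Sparc and Sfrp1 were lower in macrophages than in endothelial cells, all 4 haemoglobin genes rose (median 2.54), and Trem2 (-1.67), C5ar1 (-1.59) and Apoe (-0.92) were lower, with 2 of 11 lipid handling genes down, while Itgax did not pass (-0.03). The antigen presentation list had 5 of 8 genes up in the Lyve1 type (median 1.78) and a median of 0.11 in the intima resident type. Genes such as H2-Aa, H2-Ab1 and Cd74 also marked the intima resident type, and Lyve1 cells were not screened for free RNA from that type. The inflammatory list, whose median was 0.91 in the class, had medians of -0.63 and 0.00 within the 2 types. The haemoglobin median went opposite ways, at -1.28 in the Lyve1 type and 2.54 in the intima resident type.

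Arch and descending endothelium differed in flow, matrix and patterning genes. Several genes known to be induced by laminar flow were lower in the arch, and several that respond to disturbed flow were higher. Matrix and contractile genes were higher in the arch, beside markers of fibroblasts and smooth muscle cells, and immediate early genes were lower. The 16 smooth-muscle-like cells of the arch were too few to count as another class. Contractile genes such as Acta2 could therefore not be screened for RNA from those cells. Of 12946 genes tested, 858 were higher and 724 lower in the arch (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these 1582 genes, 386 were over 5 times higher in another class. The endothelial cells came from different clusters, since 697 and 392 of the 1246 arch cells fell in clusters 6 and 12, which held 14 and 3 cells of descending a, and 28 and 2 of descending b. Clusters 0 and 4 held 827 and 458 of the 1484 cells of descending a, and 781 and 287 of the 1290 of descending b. With no doublets removed 801 genes were called, with equal cell numbers 529, and with DESeq2 183, with 18 of the 20 named among them.

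In the laminar flow list 1 of 12 rose and 4 fell (median -0.37), and 6 fell when adjusted over the list alone. General endothelial markers moved by as much, with 1 of 11 up and 2 down, 5 down when adjusted over the list alone, and a median of -0.37. Sema3g (-2.20), Gja5 (-1.25) and S1pr1 (-0.69) fell and the water channel Aqp1 (1.28) rose. Klf2 (-0.15, edgeR adjusted p = 0.659), Klf4 (-0.27, 0.328) and Nos3 (-0.41, 0.0936) did not pass. The list median stood at percentile 0.02 of 10000 random lists matched on expression, which describes these libraries and is not a test across animals. In the disturbed flow list 6 of 15 rose and 1 fell (median 0.50), with rises in Ankrd1 (2.49), Thbs1 (0.89) and Ccn1 (0.81) and a fall in the chemokine Cx3cl1. In mesenchymal transition 5 of 11 rose, among them Acta2 (2.52 ± 0.16 SE, edgeR adjusted p = 9.32e-20), Tagln (1.94) and Fn1 (0.50). In extracellular matrix 9 of 17 rose and 1 fell, led by Col3a1 (2.70), Col1a2 (2.59) and Col1a1 (3.30), all over 5 times higher in fibroblasts, and by Sparc (1.84), which was not.

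**Figure D4:**
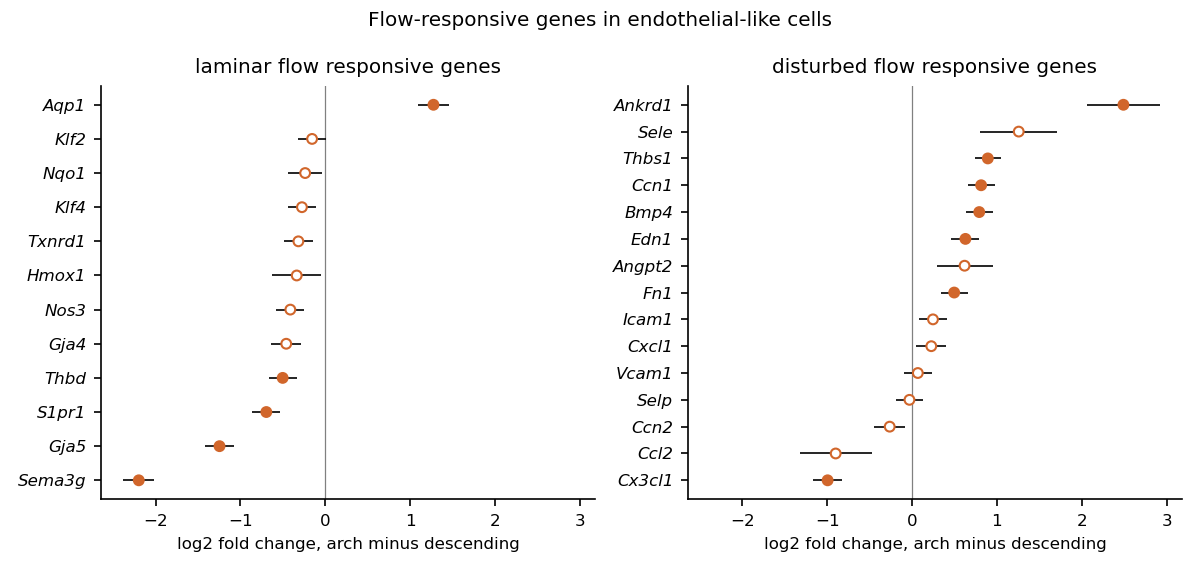
Log2 fold change, arch minus descending, of flow-responsive genes in endothelial cells. Points give the fold change and whiskers its standard error. Filled points passed an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 1 against 2 libraries).

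Clotting genes moved both ways in the arch endothelium. In the anticoagulant list 2 of 13 rose and 2 fell. The tissue plasminogen activator Plat fell (-1.92 ± 0.19 SE, edgeR adjusted p = 3.3e-12; GRCm38 chromosome 8, 22757727 to 22782844) and Thbd fell (-0.50), while Procr (0.56) and Ptgis (0.53) rose. In the procoagulant list 3 of 13 rose and 1 fell. Fgl2 (1.03) and Thbs1 rose and F5 (-1.53) fell, while Vwf did not pass (-0.38, edgeR adjusted p = 0.139). In the inflammatory list 6 of 15 rose and 2 fell, where Cxcl2 (1.96) and Ccl4 (2.61) were over 5 times higher in macrophages. In the interferon list 4 of 13 fell, among them Ifit1 (-0.74) and Irf7 (-0.58). In the dissociation and immediate early list 8 of 16 fell, led by Fos (-2.06), Btg2 (-1.19) and Zfp36 (-1.36); Fos stood at 404 and 1046 CPM in the 2 descending libraries and 165 CPM in the arch, so the size of its fall depended on the library. In senescence 3 of 12 rose and 2 fell, with Igfbp7 (1.70) up and Cdkn1a (-1.45) down. In lipid uptake 3 of 11 rose, among them Fabp4 (1.12).

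By the naming rule the largest rises were the Wnt modulator Sfrp2 (2.92), the clock output gene Dbp (2.63), Acta2, Bcas3 (2.24), Crispld2 (1.99), Tagln, Sparc, Smpd3 (1.79), Igfbp7 and Vit (1.55). At the other end, the largest falls were Ccl21a (at least 418-fold, with 0 UMIs in the arch), Lrg1 (-4.89), Shisa9 (-4.56), Sox18 (-3.00), Col8a1 (-2.31), Sema3g, Gda, the positional gene Hoxa9 (-1.96), Plat and Stbd1 (-1.85). Ccl21a marks lymphatic endothelium and belongs to a family of near-identical genes, and 5 of 6 lymphatic endothelial markers fell. RNA of other cells was also higher, with all 6 T-cell markers, all 6 mesothelial markers, 3 of 4 haemoglobin genes, 5 of 7 smooth muscle markers (median 1.94), 6 of 10 fibroblast markers (median 0.78) and 5 of 12 macrophage markers (median 0.66) up. The 6 proliferation genes that rose of 10 were over 5 times higher in T-cell-like cells.

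Clock and Hox genes were listed after the gene results had been seen. All 9 clock genes of one phase rose in arch endothelial cells (median 1.23) and 5 of 9 rose in fibroblasts (median 1.41), while 4 of 5 and 2 of 5 of the opposite phase fell. Of the Hox genes, 15 of 21 fell in endothelial cells (median -1.96) and 8 of 19 in fibroblasts (median -1.79). Hoxb9 (-3.51), Hoxb6 (-3.06) and Hoxb7 (-2.94) fell in endothelial cells. Xist had a UMI in 4, 0, 1 and 0 endothelial cells of descending a, descending b, arch and adventitia, while a Y-linked gene had a UMI in 63.7%, 58.8%, 66.1% and 44.5%.

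Arch fibroblasts carried more RNA of matrix genes than descending fibroblasts, beside more RNA of other cells. Of 11360 genes tested, 221 were higher and 125 lower (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 87 were over 5 times higher in another class. In extracellular matrix 8 of 17 rose, and 11 when adjusted over the list alone, led by Col3a1 (1.71), Sparc (1.30) and Col1a1 (1.63). In the procoagulant list 1 of 10 rose and 2 fell, with falls in Serpine2 (-2.52) and F3 (-0.93). In the interferon list 2 of 13 rose, Ifit3 (1.54) and Ifit1 (1.23). The 5 of 11 antigen presentation genes that rose were over 5 times higher in macrophages. Of the markers of other cells, 4 of 6 smooth muscle (median 2.14), 5 of 6 T-cell and 3 of 11 macrophage markers (median 0.82) rose. The largest rises by rule were Acta2 (3.38), the matricellular gene Postn, Dbp (3.03), Itm2a, Bcas3, the growth factor Igf1 (2.37), the clock gene Per3 (2.04), Mfap4, Ptprb and Tmem119. The genes that fell most were Cxcl13 (-5.90), Hp (-2.89), Spry2, Serpine2, Prg4, Hoxa7, Arhgap20, Apod, Mrgprg and Mmp3 (-1.96). Acta2 rose in all 3 classes, and the 16 smooth-muscle-like cells of the arch fell short of the 20 needed to count as another class for RNA from other cells. DESeq2 called 42 genes, with 15 of the 20 named among them, the stricter cell filter 583 and no filter on low counts 581.

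Some genes differed between arch and descending in one class and not, or oppositely, in another. Interaction tests in edgeR, adjusted by Benjamini-Hochberg (n = 1 against 2 libraries), gave 198 genes between macrophages and endothelial cells, 159 between macrophages and fibroblasts and 378 between endothelial cells and fibroblasts. Igf1 was lower in arch macrophages (-1.13) and higher in endothelial cells (2.51) and fibroblasts (2.37), and it was over 5 times higher in fibroblasts than in endothelial cells. Igf1 belongs to the Lyve1 list, and the macrophage side compared different mixes of the 2 types: in the Lyve1 type alone Igf1 stood at 333, 384 and 334 CPM in descending a, descending b and arch, and in the intima resident type at 197, 191 and 72.4 CPM. Fos was lower in arch endothelial cells (-2.06) and near level in macrophages (0.16). Sfrp2 was higher in endothelial cells (2.92) and near level in fibroblasts (0.29), and Cxcl12 was higher in endothelial cells (1.54) and lower in fibroblasts (-0.75). The interaction genes are given without the screen for RNA of other cells, and some were far higher in macrophages. Lyz1 stood at 1.51, 2.15 and 11.9 CPM in endothelial cells of descending a, descending b and arch, against 89.4 CPM in arch macrophages. Ms4a7 stood at 0, 1.37 and 8.96 CPM in fibroblasts, against 700 CPM in arch macrophages.

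The adventitia was 1 library, so layer and library could not be told apart, and the labels do not say how many mice it held. Its p-values make the same assumption about the lone library. Brown-fat and white-fat RNA was present in each adventitial class examined: Ucp1 stood at 1096 CPM in endothelial cells, 661 in macrophages, 732 in fibroblasts, 1277 in T-cell-like cells and 1109 in B-cell-like cells. Adipoq stood between 41.0 and 70.3 CPM in adventitial classes and had 0 UMIs in intimal endothelial cells.

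Taken as a class, adventitial macrophages carried more monocyte-like, procoagulant and inflammatory RNA than descending intimal macrophages, and far less of the protease and integrin genes of the intima resident type. Of 7310 genes tested, 544 were higher and 403 lower in the adventitia (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these 947 genes, 229 were over 5 times higher in another class. In the procoagulant list 8 of 13 rose and 2 fell (median 3.57 with genes lacking UMIs held at their bound), with rises in Serpinb2 (at least 86.0-fold), F10 (at least 48.9-fold), Thbs1 (4.70) and the tissue factor gene F3 (at least 11.9-fold). Vwf fell (-4.83), and Vwf was over 5 times higher in endothelial cells. In the anticoagulant list genes moved both ways, with Plaur (2.19) up and Nos3 (-4.72) down. Like Vwf, Nos3 was higher in endothelial cells than in macrophages of the intima. In the inflammatory list 13 of 18 rose and 3 fell, led by Il6 (6.20) and Cxcl1 (2.49), and in the interferon list 1 of 12 rose and 6 fell, led by Ifit3 (-3.34). All 6 monocyte markers, 3 of 5 neutrophil (median 4.72), all 3 T-cell, 2 of 3 plasma-cell and all 5 adipocyte markers rose, and Fn1 (4.64) and Ccr2 (3.13) rose. In the intima resident list 2 of 10 rose and 5 fell, and in the Lyve1 list 11 of 14 fell.

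The largest rises by rule in adventitial macrophages were Slpi (at least 1379-fold), Ucp1 (at least 153-fold), Cox8b (at least 132-fold), Alox15 (at least 93.4-fold), Serpinb2 (at least 86.0-fold), Saa3 (10.96), F10 (at least 48.9-fold), Mcemp1 (at least 27.8-fold), Thrsp (at least 25.9-fold) and F5 (at least 23.3-fold). Lowest against the descending libraries were Mmp12 (-6.23), H2-M2 (-5.60), Asb2 (-5.50), Itgax (-3.94), Mmp13 (-3.75), Zmynd15 (-3.65), Ifit3 (-3.34), Rgs1 (-3.24), AY036118 (-3.18) and Sh2d1b1 (-3.14). DESeq2 called 187 genes, equal cell numbers 502 and the Lyve1 type alone 504. In the Lyve1 type alone, a test chosen after the class result, 12 of 13 inflammatory genes and 6 of 8 antigen presentation genes rose in the adventitia, while Lyve1 did not pass (-0.41). Only 4 of the 13 procoagulant genes could be tested in that type. Their median was -0.36, so the class-level rise was not seen in these 4 and was not examined for the others. The cells compared lay in different clusters. Serpinb2, F10, Thbs1, Slpi, Saa3 and Alox15 were leading genes of a cluster of 116 macrophage-like cells found in the adventitia only, and a cluster of 15 adventitial cells of the class was led by Ccl5, Nkg7 and other genes of T and natural killer cells.

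Adventitial endothelial cells carried more RNA for fatty acid uptake than descending intimal endothelium, beside more RNA of fat cells, and flow genes moved both ways. Of 12946 genes tested, 2413 were higher and 2249 lower (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 553 were over 5 times higher in another class. In lipid uptake and transport 8 of 11 rose (median 7.58), led by Cd36 (9.79), Lpl (8.37) and Tcf15 (9.09). The same list had 6 of 11 up in adventitial fibroblasts, and fat cells were no class of their own in the screen for other classes, so how much of it belongs to the endothelium stays open. In the laminar flow list 4 of 12 rose and 4 fell, with falls in Gja5 (-4.95), Gja4 (-3.50) and Nos3 (-2.43). In the anticoagulant list 4 of 13 rose and 6 fell, led by Ptgis (-4.61), and in the procoagulant list 5 of 13 rose and 3 fell, with Vwf (-2.38) down. All 15 inflammatory genes, 14 of 16 dissociation and immediate early genes, all 4 pericyte markers and all 6 lymphatic markers rose. Markers of other cells rose beside them: all 6 adipocyte (median 8.86 with genes lacking UMIs held at their bound), 10 of 12 macrophage (median 2.60), 6 of 7 monocyte, 4 of 6 T-cell and all 4 haemoglobin genes (median 3.16). Matrix genes moved both ways (7 of 17 rose and 8 fell), with Col4a2 (3.12) up and Mgp (-4.00) and Eln (-3.94) down. The largest rises by rule were Ucp1 (at least 7086-fold), Thrsp (at least 2997-fold), Car3 (at least 1961-fold), Cfd (at least 1127-fold), Kcna5 (at least 991-fold), Car4 (13.17), Ccdc85a (at least 799.7-fold), Cidec (at least 785-fold), Adig (at least 729-fold) and Pck1 (at least 664-fold). The steepest falls were Klk10 (at least 169-fold), Isl1 (at least 54.6-fold), Nkx2-3 (at least 43.7-fold), Plekha6 (at least 29.4-fold), Pdzk1ip1 (at least 29.4-fold), Pla2g5 (at least 24.1-fold), Aldh3a1 (at least 21.9-fold), Adh7 (-9.53), Adra2a (-7.49) and Hey2 (-7.35). DESeq2 called 2057 genes.

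Adventitial fibroblasts carried more inflammatory and stress RNA than descending intimal fibroblasts, beside more RNA of other cells. Of 11360 genes tested, 1565 were higher and 1123 lower (n = 1 against 2 libraries) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 606 were over 5 times higher in another class. In extracellular matrix 8 of 17 rose and 3 fell (median 0.23), led by Col15a1 (6.45), Col4a1 (3.77) and Col4a2 (3.85). In the inflammatory list 13 of 14 rose, in the dissociation and immediate early list 12 of 16 rose, led by Fosb (3.14). Of the markers of other cells, 10 of 11 macrophage markers (median 2.41, beside 2.46 for the inflammatory list), 12 of 13 genes of the Lyve1 list and 4 of 4 haemoglobin genes rose. In the procoagulant list 6 of 10 rose and 2 fell, led by Thbs1 (4.16). The largest rises by rule, most of them fat genes, were Cox8b (at least 784-fold), Adig (at least 108-fold), Cidec (at least 107-fold), Pck1 (at least 103-fold), Ucp1 (10.68), Cfd (at least 77.9-fold), Cidea (9.67), Gmpr (9.14), Fabp3 (9.04) and Car3 (8.86). Those that fell most by rule were Akr1c18 (-4.72), Lypd2 (-4.55), Chrdl1 (-3.44), Dact2 (-3.39), Bmp3 (-3.20), AY036118 (-3.17), Smpd3 (-2.71), Tmem158 (-2.68), Cldn3 (-2.59) and Efhd1 (-2.47). DESeq2 called 573 genes and equal cell numbers 1480.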

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

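The thymocyte test and both tests of carry-over with Lyve1 macrophages were chosen after the results had been seen, and the interaction genes named were picked from their results.

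Some genes that differed between arch and descending intima did so differently in different classes. The test of the difference itself, an interaction term in edgeR with Benjamini-Hochberg adjustment, picked out 198 genes between macrophages and endothelial cells, 159 between macrophages and fibroblasts, and 378 between endothelial cells and fibroblasts. These counts rest on 1 arch library and are given without the screen for RNA of other cells. A further 2 classes of cells outside the comparisons also stood above the descending libraries in the arch. T-cell-like cells made up 7.62% of arch cells, against 0.855% and 0.861% in the descending libraries. Mesothelial-like cells made up 2.08%, against 0.101% in descending a and 0 cells in descending b, where 3 cells would have been 0.143%.

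The arch T-cell-like cells looked immature. A UMI of Rag1, Rag2, Dntt or Ptcra, which serve the building of T-cell receptors in the thymus, was found in 65.8% of them (106 of 161 cells, 95% exact interval 58.0 to 73.1, median 4369 UMIs). It was found in 0.310% of the adventitial T-cell-like cells (6 of 1935, median 1898 UMIs) and, as background, in 12.6% of arch endothelial cells (median 8394 UMIs). The thymus lies beside the aortic arch and is large in young mice, so thymus tissue carried over with the arch may account for most of these cells. A biological source of immature T cells in the young arch was not tested.

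Lyve1 macrophages are known from the adventitia, so their presence in scraped intima raised the question of carry-over. Tissue carried over with all the cell types of the adventitial library would have brought B cells along. The adventitial library held 5.2 B-cell-like cells per Lyve1 macrophage (4.57 to 5.93), while the highest descending library held 0.373 (0.208 to 0.642). This argues against carry-over of tissue with that make-up for the descending libraries. The adventitial library also held fat RNA and 164 mesothelial-like cells. Its share of B cells need not be that of adventitia left on the cleaned aorta, so carry-over of such adventitia was not excluded. The arch held 0.15 B-cell-like cells per Lyve1 macrophage (0.052 to 0.356). It held 1.1 mesothelial-like cells (0.70 to 1.73), against 0.588 (0.482 to 0.715) in the adventitia, so carry-over was not settled there. Carry-over of wall layers rich in fibroblasts and poor in lymphocytes stays open, since the intimal libraries held 5.35, 12.1 and 10.3 fibroblast-like cells per Lyve1 macrophage and the adventitial library 5.12. A Lyve1 macrophage that lives in the intima may equally explain the cells, and these counts cannot separate the 2 sources.

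The endothelial difference between arch and descending aorta was weighed against 3 technical explanations. A difference common to all cells of a library predicts like changes in fibroblasts. There the median signed change of the endothelial genes was 0.46 against 0.88 in endothelial cells, with 80.6% of 1309 genes in the same direction. The ratio of 0.526 met the bound that had been set for this explanation. The interval of the fibroblast median (0.436 to 0.509, from 1000 resamples) spans that bound and does not cover the spread between libraries. An effect of age or region shared by the classes would look the same, so the test cannot single out a technical cause, which may be part of the pattern. In macrophages, for which no bound had been set, the median was 0.57 against 0.79 in endothelial cells, with 75.3% of 871 genes in the same direction. Free RNA from other classes may account for some genes, since 24.4% of those called (386 of 1582) were over 5 times higher in another class. Tissue collected at another time of day may add to it, but the highest median change of opposite-phase clock genes over the 3 classes was -0.47, just short of the bound set, on 3 genes in macrophages. Age and region, which the design names, stay open and were not tested apart.

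The macrophage and endothelial sums of 3 libraries can be split into 3 and 3 in 10 ways. Only 1 of these 10 splits, the real one, gave as many genes (4598), and the highest other split gave 0. However, 10 splits are too few for a share under 0.05. Both classes were also clustered from these same counts, so a large difference between them was fixed by the grouping. Other splits left that difference in the residual spread, so their low counts do not test chance.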

How the results depend on the processing

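Tests of each macrophage subgroup alone and of endothelial cells without the lymphatic-marker cluster were chosen after the results had been seen.

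Of the 87 counts of genes under the alternatives, 69 stayed within 1.5 times the value reported and 18 did not. With DESeq2, 1520 genes were lower in macrophages than in endothelial cells. The arch contrasts then gave 183 genes in endothelial cells, 79 in macrophages and 42 in fibroblasts, and the adventitial contrasts 2057, 187 and 573. Of the 20 named genes of each contrast DESeq2 called 18 in arch endothelial cells, 12 in arch macrophages, 15 in arch fibroblasts and 19 in adventitial fibroblasts, and all 20 in the others. With equal cell numbers the counts were 529 for arch endothelial cells, 502 for adventitial macrophages and 1480 for adventitial fibroblasts. With no doublet removal arch endothelial cells gave 801 genes. With no filter on low counts arch macrophages gave 208 and arch fibroblasts 581, and with the stricter cell filter arch fibroblasts gave 583. The cause of these changes was not tested.

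With the intima resident subgroup alone, 1373 genes were higher in macrophages than in endothelial cells and 26 changed between arch and descending. With the Lyve1 subgroup alone, 48 changed between arch and descending and 504 between adventitia and descending. Of the class-level arch genes, 309 of the 347 tested in the Lyve1 subgroup kept their direction, and 202 of the 240 tested in the intima resident subgroup, but only 41 and 22 passed there in that direction, and 3 passed in the other direction in the Lyve1 subgroup. Without the lymphatic-marker cluster the endothelial counts were 1653 for the arch and 4717 for the adventitia.

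Leaving out each of the 3 intimal libraries in turn gave 1730 to 1761 genes higher and 1842 to 1984 lower in macrophages. Without a descending library no residual degree of freedom was left in the arch and adventitial contrasts, so only directions and fold changes were compared: 1560 of 1561 arch endothelial genes kept theirs without library a, and 1559 of 1564 without library b. Leaving out a descending library only compares the lone arch library with the other one. Nearly all called genes already had the same direction against both, and the naming rule required it, so this agreement was largely fixed in advance. Fold changes of named genes moved by more than their standard error for 39 genes without library a and for 36 without library b.

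Among shares of cells, 68 of 80 moved by less than their interval or spread and 12 moved. With each library clustered on its own, endothelial cells of descending b were 58.8% and macrophages were 5.08%, 4.64% and 7.0% in descending a, descending b and arch. At resolution 0.5 adventitial endothelial cells were 5.26%. With the stricter cell filter fibroblasts were 32.0% of descending b and 26.8% of the adventitia. T-cell-like cells of descending a went from 0.855% to 0 when it was clustered on its own, and those of the adventitia from 24.5% to 27.0% at resolution 0.5, 19.5% at resolution 2.0, 23.0% with no doublet removal and 23.3% with the stricter filter. Of 96 shares of cells with a UMI, 34 moved on thinning. Of 220 list medians recomputed over members of at least 10 CPM, 53 moved by more than their spread, such as the arch endothelial macrophage markers (0.66 to 1.38) and disturbed flow genes (0.50 to 0.37), 1 was labelled reversed and 10 changed sign. For 1 of them, the smooth muscle markers in adventitial endothelial cells (1.31 to -0.10), the first median had lain outside the range of random lists. Other sign changes were in arch endothelial procoagulant (-0.01 to 0.44), senescence (-0.07 to 0.40), dendritic (0.26 to -0.62) and plasma-cell (-0.77 to 0.07) lists, and in arch macrophage monocyte markers (-1.23 to 0.74). Of 1560 log2 fold changes of named genes, 1469 held, 75 moved on leaving out a descending library and 16 no longer passed, all with DESeq2, which gave 8 of them no adjusted p.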

Other observations

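The Hox, clock and thymocyte lists and the tests within macrophage subgroups were chosen after results had been seen, while the prediction for the clock test was written before its values were.

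Hox genes differed between the libraries. In endothelial cells 15 of 21 fell in the arch, with Hoxb9 at 48.2 and 43.3 CPM in the descending libraries and 3.82 CPM in the arch, and in fibroblasts 8 of 19 fell. Adventitial endothelial cells were low for Hoxb9 (5.44 CPM) and not for Hoxa7 (72.3 CPM, against 95.4 and 92.3 CPM in the descending libraries and 29.0 CPM in the arch). Position along the aorta, age and library were not told apart. Clock genes differed as well: Dbp was higher in the arch in endothelial cells (2.63), fibroblasts (3.03) and macrophages (1.70), though in endothelial cells its change was 1.95 without descending a and 3.92 without descending b, and there and in fibroblasts it did not pass with DESeq2. Arntl was lower in endothelial cells (-3.86) and fibroblasts (-2.76). In endothelial cells it stood at 18.6 and 6.79 CPM in descending a and b and 0.830 CPM in the arch, so the size of its fall depended on the library.

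The clock difference may reflect tissue collected at another time of day. All 9 genes of one phase rose in endothelial cells and 4 of 5 of the opposite phase fell, but in macrophages the opposite-phase median was -0.47 over 3 tested genes, none of which passed by edgeR. Times of collection would settle it. If the hour differed, every gene under clock control belongs to that difference as much as to flow or age.

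Arch macrophages differed from descending ones within each subgroup as well as in the balance of subgroups. The screen for RNA of other cells compared classes only, so free RNA from one macrophage type in the other was not examined. Antigen presentation genes such as H2-Aa, H2-Ab1 and Cd74 also marked the intima resident type, the larger type in the arch. In the Lyve1 type, Cxcl13 and Vsig4 were lower in the arch and 5 of 8 antigen presentation genes were higher. In the intima resident type, Itgax was level (-0.03) while Trem2 (-1.67) and Apoe (-0.92), genes of lipid handling, were lower. Of the lipid handling list 2 of 11 genes fell and the others did not pass, and genes richer in other cells, such as Sparc (2.99), rose in the same contrast. One hypothesis is that intimal macrophages of aged descending aorta may hold more lipid. It rests on 26 genes called in the intima resident type alone and 18 to 75 cells per library, and a lipid stain of both regions at one age would test it.

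The fibrinolytic genes Plau and Plat were divided between the cells examined. Plau was nearly absent from endothelial cells and low in the intima resident type, while the intimal Lyve1 type had only 1, 1 and 2 UMIs. Plat was expressed by endothelial cells (178 and 272 CPM in the descending libraries, 56.5 in the arch) and by fibroblasts (282 CPM in the arch), and fell in arch endothelium. In the intima resident type Plau stood at 8.86 CPM in the arch, against 28.1 and 21.2 CPM in the descending libraries, and in the Lyve1 type at 9.67 CPM against 4.28 and 3.92 CPM, all with overlapping intervals, so no rise of Plau where Plat fell was shown. A hypothesis is that macrophages may supply the urokinase of the wall; the 24.4% of arch endothelial genes that were richer in other classes did not include Plat. The hypothesis rests on few Plau UMIs. Plau levels of fibroblast-like and smooth-muscle-like cells are not given here, so these cells were not excluded as a source. A measure of fibrinolytic activity with and without macrophages at one age would test the hypothesis.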
